A study of Macaca mulatta with 9 samples.

How the data were processed

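Single-cell RNA was measured in 9 suspensions of vaginal wall from rhesus macaques (Macaca mulatta), of which the labels assign 4 to POP and 5 to Control. The labels give the same age, 15 with no unit, for each of them, and name no batch, date or animal. The deposited matrices hold raw UMI counts, with no normalization by the authors, for 21761 genes in each sample, and the deposited gene and barcode lists hold names with no measurement. Per the file headers the counts came from Cell Ranger 5.0.1. The submitters' processing notes also name STAR, the genome build Mmul_10 and Seurat 3.2, and give Seurat no role. The annotation release is not given in the sources used here. The barcodes had been restricted to called cells before deposition, and the lowest count of a barcode was 500 to 524 UMIs in each sample. A total of 72290 barcodes carried 12135660 to 59600234 UMIs per sample. Gene names came from the deposited lists and, for 594 identifiers without one, from a reference table of gene names, so that 17211 genes had a name, and 88 genes shared a name with another and were kept apart by identifier. The files give no gene positions, and the reference gene table is for another assembly, so positions are not given.

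Cells were kept with at least 300 genes, at least 500 UMIs and at most 25% of UMIs from the 13 mitochondrially encoded genes, which removed 2623 barcodes. Doublets were scored per sample with the Scrublet method in scanpy 1.11.5. Its automatic threshold marked 0 cells in 5 of the 9 samples, so the cells with the highest scores were removed up to an expected rate of 0.8% per 1000 barcodes, 5125 cells in all, and 64542 cells remained. Counts scaled to 10000 per cell and log-transformed, 2000 variable genes chosen per sample, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1.0, with all samples together and no batch integration, gave 31 clusters. Each cluster took the cell class with the highest mean z-score over marker genes. The markers covered 17 classes and 162 genes, of which 152 were in the files, and a class name required at least 3 of its markers to be detected in 25% of the cluster's cells. The clusters fell into 12 classes, and 1 cluster of 39 cells was left without a class name. Classes are called fibroblast-like and so on, because no cell was sorted or stained.

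Shares of kept cells were compared by an exact two-sided permutation test of the difference between group means over all 126 arrangements of the samples, for which 0.0079 is the smallest p, with Benjamini-Hochberg adjustment over 12 classes. For genes, raw counts were summed per sample and class. A class was tested where at least 3 samples of each group had at least 20 of its cells, which held for 10 classes and not for neutrophil-like and mast-like cells. The tool was edgeR 4.0.16 with TMM scaling, its default filter on low counts and its robust quasi-likelihood F-test, without covariates, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within the class. Levels are TMM-scaled CPM (counts scaled to a common library size), and log2 fold changes are POP minus Control. Gene lists, 24 of them with 547 genes of which 503 were in the files, and the marker lists of all cell classes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, for lists with at least 5 measured genes. The marker lists included that of the tested class itself. Those markers also named its clusters, so a call of that list may follow the make-up of the class. The p-values of edgeR, DESeq2 and camera come from models fitted across all genes of a class.

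The genes to be named were fixed before the data were examined, as were the gene lists, the markers, the tests and the alternatives. In fibroblast-like and smooth muscle-like cells these are the 10 higher and 10 lower called genes with the largest change, with a symbol and a mean of at least 5 CPM, and in the other classes 5 and 5. Of each gene list up to 4 called members are also named. COL1A1, COL3A1, ELN, FBLN5, LOXL1, MMP2, TIMP1, ACTA2, MYH11, ESR1 and PGR are named in fibroblast-like and smooth muscle-like cells whether called or not, and where no gene was called the 3 genes with the smallest p are named. Other genes named were chosen after their values were seen, and this is said where they stand.

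The alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, at least 50 cells per sample, each sample left out in turn, the replicate number as a block, doublets kept, a lenient and a strict cell filter, each cell's own marker score in place of clusters, clustering at resolution 0.5 (18 clusters) and kept cells other than epithelial-like as denominator. The lenient filter took at least 200 genes with no mitochondrial limit, and the strict one at least 500 genes, 1000 UMIs and at most 10% mitochondrial UMIs. A further 3 alternatives were added after seeing the data. They left out clusters with most of their cells from 1 sample, left out the barcodes shared by POP 2 and Control 3, and split smooth muscle-like clusters by DES. In all, 214 fits were made. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.

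The gene test was tested on simulated data, with counts drawn for each gene alone from the real depth and a fitted spread. Known changes were set in 200 genes. Such counts hold no structure shared between genes, so the rates given here need not hold for the real data. At a log2 change of 1 it called 32% of the changed genes in fibroblast-like cells, 48% in smooth muscle-like cells, 38.8% in lymphatic endothelial-like cells and 30.6% in macrophage-like cells. At a log2 change of 2 it called 81.6%, 87.5%, 94.9% and 84% in the same order. Of the unchanged genes it called 3 of 12008, 3 of 11107, 10 of 3581 and 4 of 8503 in that order, the most in lymphatic endothelial-like cells. For the share of a class in 1 sample the 95% confidence interval is Wilson's, and a count of 0 allows up to 3 counts of the total. Both cover counting error and no other spread. In the class sums, 3 counts correspond to 0.0906 to 0.623 CPM per sample in fibroblast-like cells and to 4.40 to 66.1 CPM in lymphatic endothelial-like cells. Raw reads, immunoglobulin and T-cell receptor sequences and trajectories were not analysed here.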

Results

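The data are single-cell RNA counts from 9 suspensions of rhesus macaque vaginal wall, 4 from POP and 5 from Control. The series title names spontaneous pelvic organ prolapse, and comparing POP with Control asks which cell types, and which genes within them, differ between the prolapsed and the normal vaginal wall. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples. Total UMI counts were 59600234 in POP 1, 26842167 in POP 2, 51584546 in POP 3 and 56191704 in POP 4. They were 54840809 in Control 1, 38486125 in Control 2, 12135660 in Control 3, 41854889 in Control 4 and 57771227 in Control 5. The cells kept were 9861, 4956, 8578 and 9523 in POP 1 to 4, and 7649, 5307, 1176, 8104 and 9388 in Control 1 to 5. The median UMI count of a kept cell was 3384 ± 419 (SD, n = 4) in POP and 4595 ± 1295 (SD, n = 5) in Control, with an exact permutation p = 0.0556 and an adjusted p = 0.222 over 4 measures of depth and quality. The median mitochondrial percent was 4.06 ± 1.58 (SD, n = 4) in POP and 3.17 ± 0.707 (SD, n = 5) in Control, exact permutation p = 0.318.

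The cells fell into 12 classes, and the shares of muscle and of immune cells stood farthest apart between the groups. Macrophage-like cells, many of them marked by C1QA, C1QB, CD163 and MRC1, were 2.85% ± 0.445 (SD, n = 4) of kept cells in POP and 4.98% ± 1.15 (SD, n = 5) in Control. Each of the 4 POP samples was below each of the 5 Control samples. The cluster led by C1QA, C1QB and MRC1 held 1617 cells of this class. Those led by LYZ and IL1B and by FCGR3 and CX3CR1 held 520 and 307 cells. T and NK-like cells were 10.3% ± 5.51 in POP and 22.0% ± 10.2 in Control, and B-like cells 0.733% ± 0.591 and 2.39% ± 1.65. Smooth muscle-like cells were 18.3% ± 3.19 in POP and 13.0% ± 3.11 in Control, and only some of their clusters were led by MYH11 or DES. Vascular endothelial-like cells were 13.0% ± 4.20 and 8.24% ± 4.61, pericyte-like cells 11.3% ± 1.67 and 9.04% ± 2.32, and fibroblast-like cells 33.4% ± 14.4 and 31.4% ± 9.02. Schwann-like cells were 4.60% ± 1.75 and 3.39% ± 1.10, epithelial-like cells 4.53% ± 3.59 and 2.67% ± 2.54, and lymphatic endothelial-like cells 0.432% ± 0.155 and 0.688% ± 0.439.

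None of the 12 shares passed the test after adjustment. The macrophage-like difference of -2.13 percentage points had an exact two-sided permutation p = 0.0079, the smallest that 126 arrangements can give, and an adjusted p = 0.0952. The smooth muscle-like difference of 5.29 points had an exact p = 0.0397 and an adjusted p = 0.238, and the T and NK-like difference of -11.7 points an exact p = 0.0952 and an adjusted p = 0.286. The POP sample with the highest macrophage-like share, POP 2, had 3.47% (Wilson 95% interval 2.996 to 4.02), and the Control sample with the lowest, Control 4, had 4.12% (3.71 to 4.58), so that these intervals overlapped. Neutrophil-like cells were 0.318% ± 0.241 in POP and 1.76% ± 3.11 in Control, with 0 of 1176 cells in Control 3, which allows a share of up to 0.255%. Mast-like cells were 0.188% ± 0.129 and 0.456% ± 0.271, with 0 of 4956 cells in POP 2, which allows up to 0.0605%. The direction of the fibroblast-like difference, 1.94 points, turned to -4.20 without POP 1 and to -0.540 without Control 2.

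**Figure D1:**
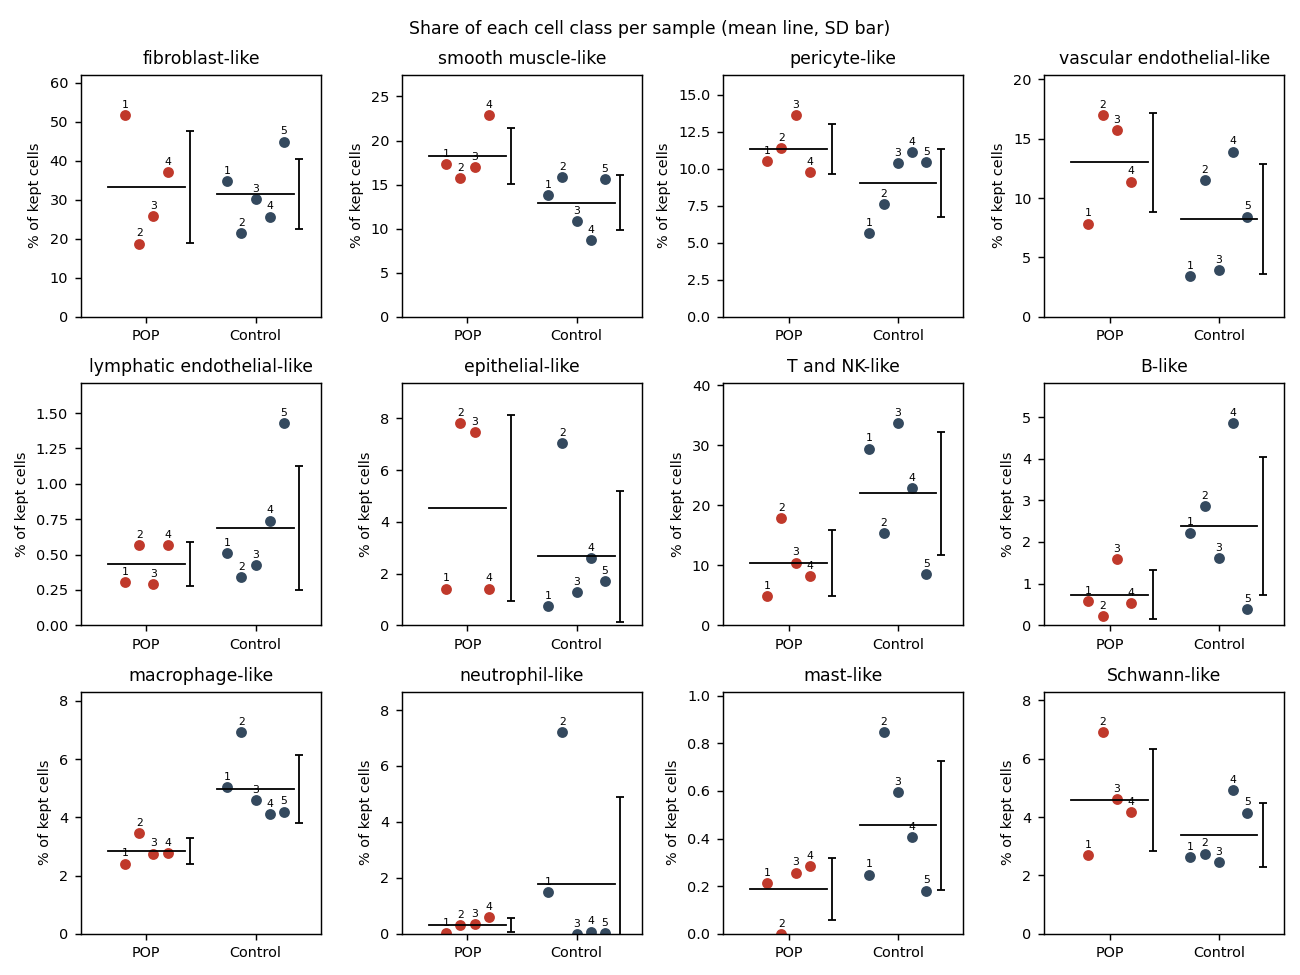
Percent of kept cells in each of the 12 cell classes, per sample, for POP and Control; points are samples with their replicate number, lines are group means and bars are SDs. The 4 POP samples lie between 2.41 and 3.47% for macrophage-like cells and the 5 Control samples between 4.12 and 6.93%.

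Lymphatic endothelial-like cells, marked by MMRN1, LYVE1, CCL21 and FLT4, held the most genes called by edgeR, while DESeq2 called the most in smooth muscle-like cells. Metallothioneins, which bind zinc and copper, fell: MT1X (ENSMMUG00000056419) was 161 ± 47.4 CPM (SD, n = 4) in POP and 1351 ± 441 CPM (SD, n = 3) in Control, a log2 fold change of -3.09 ± 0.30 (SE) at adjusted p = 1.14e-05. MT2A (ENSMMUG00000049822) was 473 ± 198 and 2621 ± 873 CPM, a log2 fold change of -2.48 ± 0.34 at adjusted p = 0.00407, and MT1E fell by 1.55 on the log2 scale. Also lower in POP were the neutrophil-attracting chemokine CXCL3 (-1.80 ± 0.32), the Wnt antagonist FRZB (-2.16 ± 0.41), the sulfotransferase SULT1C4 (-2.12 ± 0.33), the kinase scaffold AKAP12 (-1.25 ± 0.24), SPOCK2 (-1.63 ± 0.33) and TSHZ2 (-1.68 ± 0.34). Higher in POP were SERPINH1, the chaperone of collagen folding (2.01 ± 0.38), SDF2L1, a protein of the endoplasmic reticulum induced by misfolded protein (1.96 ± 0.36), and HSPG2, the basement membrane proteoglycan perlecan (1.49 ± 0.29). For each of these 12 genes the 4 POP samples lay on one side of the 3 Control samples. MT1E, AKAP12, SPOCK2 and TSHZ2 lay outside the rule for named genes and were chosen after their values were seen.

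The 12 genes, 3 higher and 9 lower in POP, were those called by edgeR among 3959 tested, and DESeq2 called 18, with all 12 among them. The 7 samples tested had 25 to 134 of these cells each, while Control 2 with 18 cells and Control 3 with 5 had too few. In these 2 samples, on counts not scaled by TMM, MT1X was 779 and 903 CPM and MT2A 4789 and 749 CPM, above the highest POP sample at 182 and 583 CPM. CXCL3, however, was 47.5 and 44.1 CPM in them, below the lowest POP sample at 88.2 CPM. FRZB and SPOCK2 were not above the highest POP sample in either. SULT1C4 was 9.50 CPM and TSHZ2 14.25 CPM in Control 2, below the lowest POP sample at 18.3 and 19.7 CPM. Such levels are near the floor, since 3 counts make 14.25 CPM there. Both had 0 counts in Control 3, which allows up to 66.1 CPM. That limit is below the lowest tested Control, at 135 and 93.8 CPM, but above the highest POP sample, at 48.6 and 54.8 CPM. SDF2L1 was 190 CPM in Control 2, above the highest POP sample at 140 CPM. HSPG2 was 264 CPM in Control 3, above the highest POP sample at 227 CPM, AKAP12 was 220 CPM in Control 3, below the lowest POP sample at 539 CPM, and MT1E was 969 CPM in Control 2, within the POP range of 617 to 1029 CPM. Leaving out 1 sample gave 6 calls without POP 1, 46 without POP 2, 8 without POP 3, 3 without POP 4, 21 without Control 1, 7 without Control 4 and 8 without Control 5. MT1X and SULT1C4 were called in each case. With doublets kept and with each cell's own score, however, which also bring Control 2 into the test, MT1X was the 1 gene called (SULT1C4 had an adjusted p = 0.293 with doublets kept), and the strict filter left 5 genes. SDF2L1 turned to -0.20 with each cell's own score. MT2A was lost without POP 4 (adjusted p = 0.0626), MT1E without POP 4 (0.0626) or Control 5 (0.0569), and CXCL3 without POP 1 (0.0952), POP 3 (0.0578), Control 4 (0.107) or Control 5 (0.111). FRZB was lost without POP 3 (0.0744), POP 4 (0.302), Control 4 (0.0666) or Control 5 (0.14). TSHZ2 was lost without POP 3 (0.052), POP 4 (0.3), Control 4 (0.121) or Control 5 (0.102), and SPOCK2 without POP 1 (0.112), POP 3 (0.0568), POP 4 (0.292), Control 4 (0.0666) or Control 5 (0.187). SERPINH1 was lost without POP 1 (0.0901), POP 4 (0.202), Control 1 (0.0507), Control 4 (0.107) or Control 5 (0.147). SDF2L1 was lost without POP 1 (0.0599), POP 4 (0.169), Control 4 (0.107) or Control 5 (0.135). HSPG2 was lost without POP 1 (0.0652), POP 3 (0.0662), POP 4 (0.169), Control 4 (0.107) or Control 5 (0.165). AKAP12 was lost without POP 1 (0.0524), POP 3 (0.0662), POP 4 (0.123), Control 1 (0.0634), Control 4 (0.1) or Control 5 (0.102).

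Among the gene lists in lymphatic endothelial-like cells, 5 were called higher and 4 lower by camera out of 25 tested at the preset correlation, and 0 with an estimated one. The list of the unfolded protein response had a median log2 fold change of 0.80, with 12 of its 15 members above 0. Of these, 1 member rose over all genes tested and 8 rose adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, was 822 ± 307 CPM (SD, n = 4) in POP and 354 ± 43.2 CPM (SD, n = 3) in Control, and calreticulin (CALR) 1153 ± 496 and 524 ± 211 CPM. The list of cell cycle genes (median 0.98, 5 of 5 members above 0, 3 adjusted over the list alone), that of heat shock genes (median 0.37, 10 of 13, 3 adjusted over the list alone) and that of nuclear-encoded oxidative phosphorylation (median 0.38, 31 of 34, 0 adjusted over the list alone) were also called higher. Examples were PCNA, the sliding clamp of DNA replication, at 163 ± 79.3 and 66.1 ± 7.92 CPM, and the mitochondrial chaperone HSPD1 at 252 ± 140 and 103 ± 30.2 CPM. NF-kB and cytokine genes (median -1.24, 4 of 5 members below 0, 1 lower over all genes tested and 3 adjusted over the list alone) and immediate early genes (median -0.84, 12 of 12 below 0, 0 adjusted over the list alone) were called lower, with NFKBIA, the inhibitor of NF-kB, at 492 ± 190 and 958 ± 408 CPM and JUN at 308 ± 69.6 and 553 ± 199 CPM. In the left-out Control 2, on counts not scaled by TMM, HSPA5 was 1601 CPM and HSPD1 703 CPM, above the highest POP sample at 1104 and 389 CPM, and JUN was 304 CPM in Control 2 and 132 CPM in Control 3, not above the highest POP sample at 353 CPM. In the fits with each cell's own score, which include Control 2, the median turned to -0.12 for the unfolded protein response and to -0.24 for heat shock, and with doublets kept, also including Control 2, to 0.0711 and -0.21. The weakest medians over the alternatives were -0.455 for NF-kB and cytokine genes, -0.222 for immediate early genes and 0.112 for oxidative phosphorylation. Each of these calls was lost in 1 alternative that left out no sample (camera adjusted p = 0.217, 0.101 and 0.131). HSPA5, CALR, PCNA, HSPD1, NFKBIA and JUN did not pass over all genes with edgeR and were chosen after their values were seen. HSPA5 passed with DESeq2 (adjusted p = 0.0472), without POP 2 (0.0334) and without the filter on low counts (0.00669), and PCNA without POP 2 (0.0118). Without that filter PCNA (0.0161), CALR (0.0141), HSPD1 (0.0252) and NFKBIA (0.0383) passed too.

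Of the other 3 lists called in these cells, mitochondrially encoded genes had a median of 0.42, antigen presentation -0.70 and fibroblast markers -0.60. Antigen presentation was not called without POP 1 (adjusted p = 0.119) or Control 1 (0.994, median -0.0797), mitochondrially encoded genes not without POP 2 (0.326) or Control 5 (0.238), and fibroblast markers not without POP 2 (0.155), POP 3 (0.17, median -0.391) or Control 1 (0.0872). The fibroblast marker APOD, an abundant lipid-binding protein, was 128 ± 92.4 CPM (SD, n = 4) in POP and 3174 ± 3094 CPM (SD, n = 3) in Control in these cells, and did not pass with edgeR but passed with DESeq2 (adjusted p = 0.00143) and without Control 5 (0.00591). With an estimated correlation no list was called, at adjusted p = 0.279 for the unfolded protein response, 0.452 for cell cycle and immediate early genes, 0.456 for heat shock and oxidative phosphorylation and 0.279 for NF-kB and cytokine genes. The other 3 lists had adjusted p = 0.456 to 0.499 with an estimated correlation. The medians moved without Control 1 to -0.714 for NF-kB and cytokine genes and to 1.64 for cell cycle, without POP 4 to 0.242 and without Control 4 to 0.253 for oxidative phosphorylation, without Control 5 to -1.07 for antigen presentation, and for fibroblast markers to -0.22 without Control 4 and -0.163 without Control 5.

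**Figure D2:**
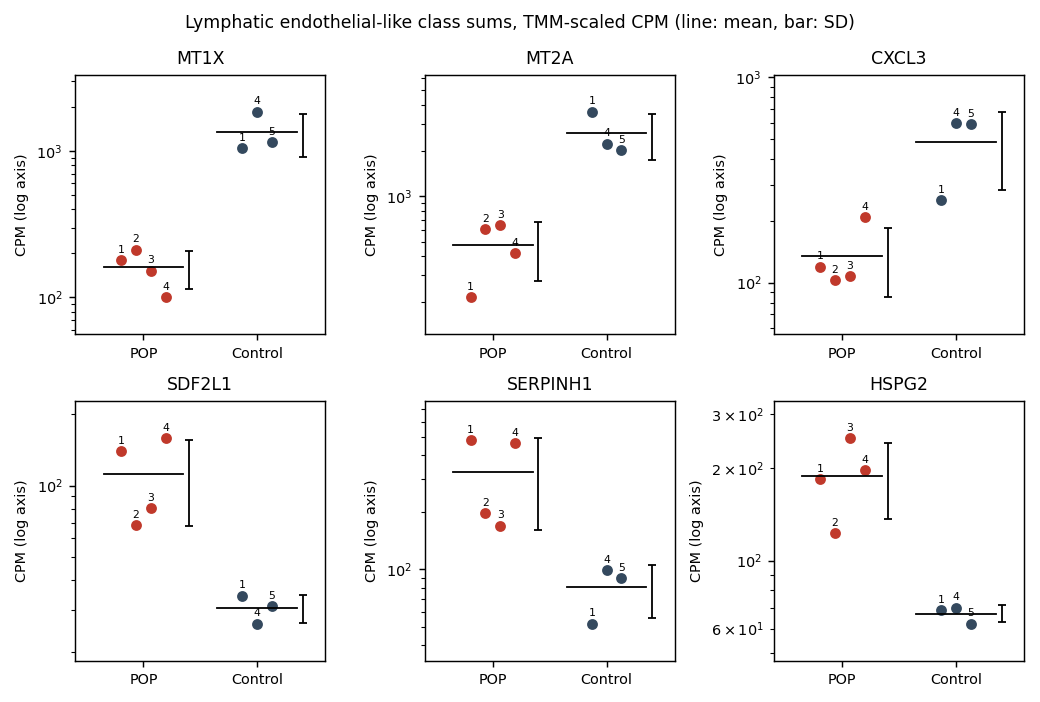
TMM-scaled CPM, on a log axis, of 6 genes in lymphatic endothelial-like cells, per sample; points are samples with their replicate number, lines are means and bars SDs. MT1X lies between 100.1 and 212 CPM in the 4 POP samples and between 1042 and 1857 CPM in the 3 Control samples.

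In macrophage-like cells the chemokine CXCL14 (ENSMMUG00000004771), which is also made by fibroblasts and epithelium, rose. It was 104 ± 23.2 CPM (SD, n = 4) in POP and 19.9 ± 8.04 CPM (SD, n = 5) in Control, a log2 fold change of 2.34 ± 0.28 (SE) at adjusted p = 0.0363, and was higher in 4 of 4 POP samples than in any Control sample. It was the 1 gene called by edgeR among 8766, with 319 at an unadjusted p under 0.05, and DESeq2 called 4. CD163, the haemoglobin scavenger receptor of macrophages, was 607 ± 172 CPM in POP and 1270 ± 225 CPM in Control, APOD 79.2 ± 41.7 and 17.1 ± 6.36 CPM, and FKBP5, a co-chaperone of steroid receptors, 177 ± 52.8 and 347 ± 99.1 CPM. These 3 genes did not pass with edgeR and were chosen after their values were seen, while CD163 (adjusted p = 0.0317) and APOD (0.00285) passed with DESeq2. The call of CXCL14 was lost without POP 1 (adjusted p = 0.228), POP 2 (0.212), POP 3 (0.24), Control 1 (0.19), Control 4 (0.215) or Control 5 (0.112), with doublets kept (1.0) and with classes from each cell's own score (0.428), and in the fit with the replicate number as a block, which also drops Control 5 (0.231), while its log2 fold change stayed between 1.84 and 2.53 over the alternatives.

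Camera called 4 of 32 lists in macrophage-like cells at the preset correlation, and none of them with an estimated one (adjusted p = 0.932 for all 4). NF-kB and cytokine genes were called higher (median 0.46, 15 of 18 members above 0, 0 adjusted over the list alone), with the neutrophil-attracting chemokine CXCL1 at 7.92 ± 2.84 and 3.21 ± 2.38 CPM. Collagens had a median of 1.10 with 9 of 9 members above 0, antioxidant genes 0.30 with 14 of 21 above 0, and steroid hormone receptors and targets -0.15 with 7 of 12 below 0. COL3A1, a fibrillar collagen that macrophages are not known to make in quantity, was 124 ± 151 and 33.8 ± 17.0 CPM and was as high as 345 CPM in 1 POP sample. The call of NF-kB and cytokine genes was lost without POP 4 (adjusted p = 0.145, median 0.188), and its median was 0.216 without POP 3. Collagens were lost without POP 1 (0.928, median 0.123), Control 2 (0.144), Control 3 (0.0924) or Control 4 (0.0568), and antioxidant genes without POP 1 (0.0844), POP 3 (0.126, median 0.101), POP 4 (0.159, median 0.138), Control 3 (0.267) or Control 4 (0.0568). Steroid hormone receptors and targets were lost without POP 1 (0.208, median 0.0764), POP 2 (0.0747, median -0.0164), POP 3 (0.0612), Control 3 (0.0766), Control 4 (0.0568) or Control 5 (0.131), and their median was -0.274 without POP 4 and -0.283 without Control 2.

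In smooth muscle-like cells camera called the genes of the contractile apparatus lower in POP at the preset correlation, but not with an estimated one (adjusted p = 0.647), and no single member passed over all genes with edgeR, while SYNM did with DESeq2 (adjusted p = 0.0376). The list of smooth muscle contraction genes had a median log2 fold change of -0.43, with 23 of 24 members below 0, and the list of smooth muscle markers one of -0.76, with 11 of 12 below 0. The markers also served to name the class, so their fall may follow its make-up. MYH11, the smooth muscle myosin heavy chain (ENSMMUG00000010367), was 5206 ± 1405 CPM (SD, n = 4) in POP and 9414 ± 2714 CPM (SD, n = 5) in Control. The intermediate filament proteins SYNM and DES were 197 ± 97.2 against 542 ± 224 CPM and 498 ± 312 against 1193 ± 556 CPM, and MYLK, the kinase that starts contraction, was 1112 ± 258 against 1781 ± 463 CPM. ACTA2, the smooth muscle actin, went the other way at 7728 ± 799 and 6634 ± 1324 CPM. SYNM, DES and MYLK were chosen after their values were seen.

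Camera called these 2 lists of 33, at adjusted p = 3.44e-11 and 1.55e-06, and both were called without any 1 sample. With an estimated correlation neither was called, and the lowest adjusted p of any list was 0.647. Adjusted over the list alone, 0 contraction genes and 2 marker genes were lower. The cells of the clusters with DES among their leading genes, which are visceral rather than vascular smooth muscle by their markers, were 22.9% ± 16.0 (SD, n = 4) of smooth muscle-like cells in POP and 37.3% ± 16.9 (SD, n = 5) in Control, exact permutation p = 0.238. The median of the contraction list was -0.20 in the other clusters alone and -0.35 in the clusters with DES alone. Of the latter, the cluster led by ACTG2 and DES held 2, 0, 200 and 36 cells of POP 1 to 4 and 244, 375, 1, 87 and 376 cells of Control 1 to 5, so the value of -0.35 is not a difference within like cells. Of the clusters without DES, that led by PRPH, PGF and RERGL was 9.12% of kept cells in POP and 4.13% in Control. That led by P2RX1 was 4.80% and 3.63%. The value of -0.20 may therefore also reflect a mix of clusters.

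edgeR called 0 single genes among 11477 in smooth muscle-like cells, with 800 at an unadjusted p under 0.05, and DESeq2 called 22. The 3 genes with the smallest p, none of which passed with edgeR, were CD248, a surface protein of mesenchymal and perivascular cells, at 39.0 ± 4.94 and 20.01 ± 3.11 CPM, CD163 at 0.364 ± 0.141 and 2.39 ± 0.528 CPM, and the calcium-dependent kinase CAMK2G at 51.5 ± 7.47 and 88.8 ± 10.6 CPM (SD, n = 4 and n = 5). With DESeq2 all 3 passed, at adjusted p = 0.000859, 0.0376 and 0.000859. CD163 is a macrophage marker. Its 0.181 to 0.514 CPM in POP lay near the floor, where 3 counts make 0.401 to 1.01 CPM per sample. Of the genes fixed in advance, COL1A1 was 692 ± 559 and 457 ± 106 CPM, COL3A1 417 ± 209 and 319 ± 88.0 CPM, ELN, which encodes elastin, 47.5 ± 23.1 and 52.5 ± 30.3 CPM, FBLN5 13.7 ± 12.6 and 11.6 ± 4.59 CPM and LOXL1, which crosslinks elastin, 68.7 ± 37.1 and 44.5 ± 8.20 CPM. The protease MMP2 was 40.4 ± 22.1 and 35.9 ± 14.5 CPM and its inhibitor TIMP1 862 ± 162 and 682 ± 170 CPM. The oestrogen receptor ESR1 was 209 ± 102 and 114 ± 79.9 CPM and the progesterone receptor PGR 24.7 ± 8.81 and 17.7 ± 7.78 CPM.

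**Figure D3:**
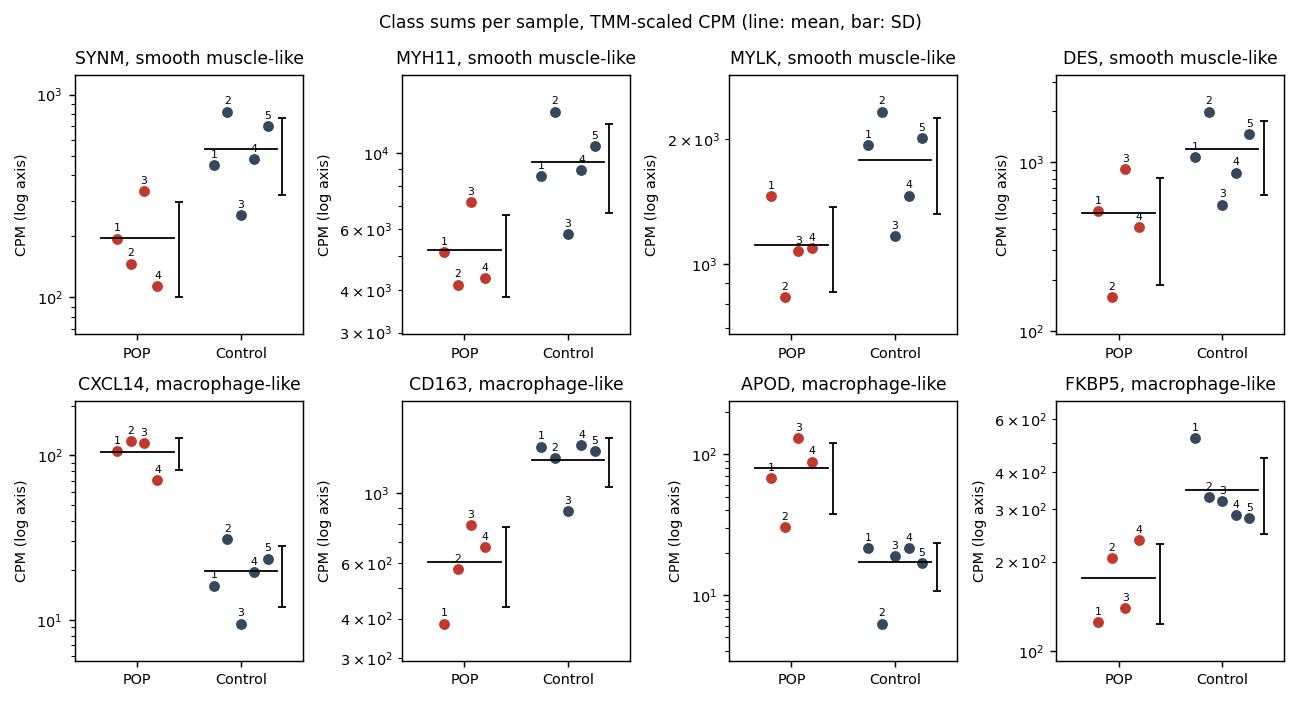
TMM-scaled CPM, on a log axis, of SYNM, MYH11, MYLK and DES in smooth muscle-like cells and of CXCL14, CD163, APOD and FKBP5 in macrophage-like cells, per sample; points are samples with their replicate number, lines are means and bars SDs. CXCL14 lies between 70.9 and 122 CPM in the 4 POP samples and between 9.48 and 30.9 CPM in the 5 Control samples.

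In fibroblast-like cells the fibrillar collagens had similar group means and a wide spread. COL1A1 was 14300 ± 7537 CPM (SD, n = 4) in POP and 14310 ± 8514 CPM (SD, n = 5) in Control, and COL3A1 7367 ± 2722 and 7211 ± 4410 CPM. With 1 sample left out the log2 fold change of COL1A1 ran from -0.35 to 0.40. The fibroblast-like clusters were filled unequally: that led by COL1A1 and COL3A1 was 24.4% of kept cells in POP 1 and 1.83 to 6.63% in the other samples, so the class means may also reflect this mix. Elastin (ELN) was 300 ± 81.1 and 336 ± 100.3 CPM, FBLN5, which anchors elastic fibres, 224 ± 74.4 and 245 ± 53.5 CPM, LOXL1 196 ± 75.1 and 137 ± 54.6 CPM, MMP2 1563 ± 253 and 1764 ± 351 CPM and TIMP1 4305 ± 1829 and 2756 ± 1274 CPM. ESR1 was 438 ± 58.4 CPM in POP and 244 ± 96.3 CPM in Control, with 4 of 4 POP samples above the 5 Control samples, and PGR was 63.3 ± 28.0 and 51.4 ± 27.9 CPM. ACTA2 was 50.8 ± 14.9 and 50.5 ± 14.0 CPM and MYH11 22.9 ± 9.96 and 42.2 ± 23.7 CPM. None of these genes passed with edgeR or DESeq2. edgeR called 0 of 12334 genes, with 546 at an unadjusted p under 0.05, and DESeq2 called 11. The 3 genes with the smallest p were ENSMMUG00000060971 at 1.14 ± 0.228 and 0.262 ± 0.0484 CPM, TNFRSF19 at 17.6 ± 4.82 and 8.10 ± 0.891 CPM and the glucose transporter SLC2A8 at 3.76 ± 1.16 and 13.7 ± 5.4 CPM. Their adjusted p was 0.653 with edgeR, and with DESeq2 TNFRSF19 (0.012) and SLC2A8 (0.00124) passed.

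Camera called 6 of 33 lists in fibroblast-like cells, 2 higher and 4 lower in POP, at the preset correlation, and 0 with an estimated one (lowest adjusted p = 0.0686). The cell cycle list was higher (median 0.34, 14 of 15 members above 0, 0 adjusted over the list alone), with the DNA synthesis genes TYMS at 12.5 ± 3.02 and 5.98 ± 2.17 CPM and MCM3 at 6.03 ± 4.02 and 2.49 ± 0.731 CPM (SD, n = 4 and n = 5). The list of steroid hormone receptors and targets was lower (median -0.23, 13 of 17 below 0), with 3 members lower and 1 higher adjusted over the list alone. FKBP5 was 35.7 ± 25.5 and 149 ± 65.4 CPM, TSC22D3 238 ± 87.9 and 539 ± 124 CPM and ZBTB16 78.1 ± 40.3 and 210 ± 68.8 CPM, all induced by glucocorticoids. Macrophage markers had a median of -0.40, with 8 of 10 below 0 and 2 lower adjusted over the list alone, and T and NK markers one of -0.66, with 12 of 12 below 0. C1QB was 2.34 ± 1.29 and 7.69 ± 3.03 CPM, CD163 0.530 ± 0.245 and 2.28 ± 0.693 CPM and CD3D 1.80 ± 1.18 and 4.17 ± 2.46 CPM. These are leukocyte genes at low levels, with CD163 at 0.205 CPM in POP 2, where 3 counts make 0.623 CPM. Leukocyte-like cells were 14.4% of kept cells in POP and 31.6% in Control. Whether stray leukocyte RNA or doublets account for the calls of these marker lists was not tested. Complement had a median of -0.23, with C7 at 412 ± 258 and 820 ± 417 CPM, and heat shock one of 0.18, with DNAJB1 at 153 ± 91.8 and 96.6 ± 15.9 CPM. The genes named here did not pass over all genes with edgeR and were chosen after their values were seen, while DESeq2 gave adjusted p = 0.0366 for FKBP5 and 0.0352 for CD163. Heat shock was lost without POP 4 (adjusted p = 0.0595), Control 3 (0.0646) or Control 4 (0.0781), with medians of 0.278 without POP 1, 0.295 without Control 1 and 0.306 without Control 2. The steroid list was lost without POP 1 (0.289, median -0.0649), Control 1 (0.0861), Control 2 (0.055) or Control 3 (0.131). Complement was lost without POP 1 (0.372, median -0.146), Control 1 (0.0989) or Control 4 (0.0776), with medians of -0.352 without POP 4 and -0.129 without Control 2. T and NK markers were lost without POP 1 (0.414), POP 4 (0.0652), Control 1 (0.11) or Control 3 (0.499, median -0.216), with a median of -1.27 without POP 3. Macrophage markers had medians of -0.781 without POP 3 and -0.62 without POP 4, and were not called without the barcodes shared by POP 2 and Control 3 (0.355). Counting those that left out no sample, 5 of 20 alternatives did not keep the steroid call. For complement and for T and NK markers it was 5 each, and for macrophage markers 2. With an estimated correlation the adjusted p was 0.0686 for cell cycle, 0.676 for macrophage markers and 0.755 to 0.866 for the others.

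Vascular endothelial-like cells, marked by VWF, EMCN and ACKR1, had CA4, a carbonic anhydrase of capillaries, at 10.5 ± 3.99 CPM (SD, n = 4) in POP and 41.3 ± 12.04 CPM (SD, n = 5) in Control. APOD was 167 ± 33.4 and 785 ± 336 CPM, and the ephrin receptor EPHA7 5.33 ± 2.03 and 1.28 ± 0.736 CPM. Camera called TGF-beta signalling higher (median 0.20, 17 of 22 members above 0, 0 adjusted over the list alone), with TGFB2 at 12.3 ± 1.78 and 6.32 ± 5.13 CPM. Neither this call nor the next held with an estimated correlation (adjusted p = 0.861 and 0.991). It called hypoxia and glycolysis lower (median -0.41, 17 of 19 below 0, 0 adjusted over the list alone), with hexokinase HK2 at 1.66 ± 0.961 and 6.93 ± 6.69 CPM and enolase ENO1 at 265 ± 39.7 and 407 ± 203 CPM. ESR1 was 15.2 ± 4.03 and 6.002 ± 2.74 CPM. TGFB2, HK2, ENO1 and ESR1 were chosen after their values were seen.

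edgeR called 0 of 10745 genes in these cells, with 842 at an unadjusted p under 0.05, and DESeq2 called 12. CA4, APOD and EPHA7 had the 3 smallest p, each at adjusted p = 0.339, and passed with DESeq2 (3.81e-05, 7.09e-07 and 0.0341). CA4 passed without Control 4 (adjusted p = 0.0388) and APOD without Control 5 (0.000667). Both list calls had adjusted p = 0.0407. TGF-beta signalling was lost without POP 2 (0.0556), Control 3 (0.131) or Control 4 (0.056), and hypoxia and glycolysis without POP 1 (0.279), POP 2 (0.0556) or Control 2 (0.835, median -0.15). Leaving out the barcodes shared by POP 2 and Control 3 ended both calls. Of 20 alternatives, 7 did not keep the TGF-beta call and 5 that of hypoxia and glycolysis.

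Pericyte-like cells, marked by RGS5 and HIGD1B, had the epoxide hydrolase EPHX1 at 166 ± 19.6 CPM (SD, n = 4) in POP and 95.0 ± 20.5 CPM (SD, n = 5) in Control. LAGE3 was 31.7 ± 3.48 and 51.8 ± 4.93 CPM and TYW1, which modifies a transfer RNA, 12.6 ± 0.431 and 22.0 ± 2.79 CPM. These 3 genes had the smallest p and did not pass, at adjusted p = 0.772. edgeR called 0 of 10177 genes, with 640 at an unadjusted p under 0.05, DESeq2 called 0, and camera called 0 of 29 lists.

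In epithelial-like cells, marked by KRT5, KRT13 and DSP, camera called hypoxia and glycolysis genes lower in POP at the preset correlation, but not with an estimated one (adjusted p = 0.919). The list had a median of -0.47, with 18 of 19 members below 0 and 0 adjusted over the list alone. Its members CA9 and HIF1A, a carbonic anhydrase and the transcription factor of the hypoxia response, were 2.35 ± 1.06 and 8.96 ± 6.52 CPM, and 206 ± 31.3 and 367 ± 179 CPM (SD, n = 4 in POP and n = 4 in Control). The interferon-induced MX1 was 39.5 ± 6.81 and 97.3 ± 18.8 CPM, and the type I interferon list had a median of -0.25, with 16 of 22 below 0 and 1 adjusted over the list alone. USP18, which limits interferon signalling, was 3.68 ± 1.31 and 11.9 ± 6.43 CPM. The unfolded protein response had a median of -0.38, with ASNS, which makes asparagine, at 6.13 ± 2.29 and 15.7 ± 6.77 CPM, ribosomal proteins one of 0.17 and smooth muscle markers one of -0.55. CA9, HIF1A, USP18 and ASNS were chosen after their values were seen.

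Camera called these 5 of 29 lists, while edgeR called 0 of 10087 genes, with 590 at an unadjusted p under 0.05, and DESeq2 called 2. MX1, GPAT3 (4.14 ± 1.45 and 19.3 ± 7.67 CPM) and ADAMTSL4 (7.93 ± 0.908 and 22.8 ± 8.07 CPM) had the 3 smallest p, at adjusted p = 0.445, 0.783 and 0.844, and MX1 (0.000384) and GPAT3 (0.00289) passed with DESeq2. The hypoxia and glycolysis call held without each sample in turn, with a median of -0.308 without Control 1, and the unfolded protein response was lost without POP 2 (0.0668) or Control 2 (0.0733, median -0.135). Type I interferon was lost without POP 3 (0.205, median -0.0765), POP 4 (0.0616) or Control 1 (0.373), with medians of -0.391 without POP 1 and -0.404 without Control 2. Ribosomal proteins were lost without POP 3 (0.316, median 0.0884), POP 4 (0.268, 0.069), Control 1 (0.0567, 0.115), Control 2 (0.2, 0.0921) or Control 4 (0.0625), with medians of 0.28 without POP 1 and 0.327 without Control 5. Smooth muscle markers were lost without POP 1 (0.0627), POP 2 (0.199, median -0.196), POP 3 (0.238, -0.318), Control 1 (0.176, -0.332) or Control 5 (0.559, -0.24), with medians of -1.15 without POP 4 and -0.894 without Control 4. All 5 had an adjusted p = 0.919 with an estimated correlation.

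In T and NK-like cells, marked by CD3E, NKG7 and IL7R, the 3 genes with the smallest p were the transcription factor ZEB2 at 57.4 ± 9.18 CPM (SD, n = 4) in POP and 29.5 ± 4.08 CPM (SD, n = 5) in Control, PAOX, an oxidase of polyamines, at 59.4 ± 3.78 and 113 ± 25.8 CPM, and RGS5 at 14.7 ± 4.84 and 4.98 ± 1.13 CPM. RGS5 is a pericyte marker. None passed with edgeR, at adjusted p = 0.269, 0.318 and 0.318, and all 3 passed with DESeq2, at 0.00207, 0.0092 and 0.0092. Camera called ribosomal proteins lower (median -0.25, 62 of 65 members below 0) and heat shock (median 0.27, 12 of 14 above 0), TGF-beta signalling (0.20, 13 of 15) and proteoglycans and matrix glycoproteins (0.30, 13 of 14) higher, with 0 members of any of them adjusted over the list alone. None of the 4 held with an estimated correlation (adjusted p = 0.937). The mix of T and NK-like clusters differed as well: that with IL7R among its leading genes was 2.20% of kept cells in POP and 7.89% in Control, with 17.7% in Control 4, and a cluster with a median of 817.5 UMIs was 4.54% in POP 2 and 0.639 to 1.78% in the other samples. HSPB1 was 65.6 ± 37.9 and 32.9 ± 13.3 CPM, ID1 14.0 ± 6.13 and 7.84 ± 3.11 CPM and BGN, a matrix proteoglycan, 9.57 ± 7.93 and 4.07 ± 1.49 CPM. HSPB1, ID1 and BGN were chosen after their values were seen. edgeR called 0 of 8751 genes, with 463 at an unadjusted p under 0.05, and DESeq2 called 6. The call of ribosomal proteins was lost without POP 2 (adjusted p = 0.131, median -0.0822), that of heat shock without POP 3 (0.0932), that of TGF-beta without POP 3 (0.0932), POP 4 (0.18), Control 2 (0.0644) or Control 4 (0.076), and that of proteoglycans without POP 1 (0.787, median -0.0164), POP 3 (0.0932, 0.474), Control 2 (0.205, 0.15), Control 3 (0.0998) or Control 4 (0.335, 0.178). Other medians were 0.513 without POP 2 and 0.673 without Control 5 for proteoglycans, 0.0866 without POP 4 and 0.305 without Control 3 for TGF-beta, and -0.165 without Control 4 for ribosomal proteins.

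In B-like cells, which also held plasma cell markers such as JCHAIN, camera called cell cycle genes higher in POP at the preset correlation, but not with an estimated one (adjusted p = 0.678). The list had a median of 1.03, with 17 of 20 members above 0 and 4 higher adjusted over the list alone, and a median of 0.185 (adjusted p = 0.984) with classes from each cell's own score. TYMS was 137 ± 72.2 CPM (SD, n = 3) in POP and 28.9 ± 19.6 CPM (SD, n = 4) in Control, RRM2, a subunit of ribonucleotide reductase, 265 ± 114 and 59.7 ± 40.2 CPM, and the proliferation marker MKI67 155 ± 52.2 and 66.7 ± 27.4 CPM. B markers, which also served to name the class, had a median of -0.64, with 7 of 7 below 0 and CD79B at 428 ± 210 and 780 ± 310 CPM. The T-cell marker CD2 was 28.0 ± 16.2 and 2.53 ± 2.33 CPM, and ENSMMUG00000052929 271 ± 300 and 2.55 ± 1.75 CPM. Antioxidant genes (median 0.40, 14 of 18 above 0), heat shock genes (0.42, 11 of 12), smooth muscle contraction genes (1.41, 10 of 12, 3 adjusted over the list alone) and collagens (1.98, 8 of 8) were also called higher, with COL6A3 at 137 ± 198 and 11.5 ± 11 CPM. None of these calls held with an estimated correlation (adjusted p = 0.427 to 0.9). RRM2, MKI67, CD79B and COL6A3 were chosen after their values were seen.

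edgeR called 0 of 6228 genes in B-like cells, with 418 at an unadjusted p under 0.05, and DESeq2 called 2. TYMS, CD2 and ENSMMUG00000052929 had the 3 smallest p, each at adjusted p = 0.705, and TYMS (0.0126) and ENSMMUG00000052929 (3.1e-10) passed with DESeq2. edgeR called 1 gene without POP 3, 1 without POP 4 and 2 without Control 1, with ENSMMUG00000052929 at 0.0132 without POP 3 and 0.0482 without POP 4. Of the 6 list calls among 25, cell cycle and antioxidant held without each sample, with an antioxidant median of 0.199 without POP 1. The antioxidant median turned to -0.03 with each cell's own score, however. Heat shock was lost without POP 1 (adjusted p = 0.0621), with a median of 0.638 without Control 1, and contraction genes without POP 1 (0.485, median 0.0862) or POP 3 (0.0937). Collagens were lost without POP 1 (0.975, median -0.677), POP 3 (0.0918), Control 2 (0.262), Control 4 (0.106) or Control 5 (0.476), with a median of 3.4 without Control 1. B markers were lost without POP 1 (0.677, median -0.2), Control 2 (0.0583) or Control 5 (0.0697), with a median of -1.02 without POP 3. With an estimated correlation the adjusted p was 0.678 for cell cycle, 0.427 for antioxidant, 0.678 for heat shock and 0.9 for the other 3.

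In Schwann-like cells, marked by CDH19 and S100B, camera called type I interferon genes lower in POP at the preset correlation, but not with an estimated one (adjusted p = 0.91). The list had a median of -0.93, with 21 of 22 members below 0 and 0 adjusted over the list alone, and a median of -0.15 without Control 1, which held the highest OAS1 (150.0 CPM) and USP18 (60.6 CPM). The antiviral OAS1 was 7.91 ± 4.97 CPM (SD, n = 4) in POP and 48.9 ± 57.2 CPM (SD, n = 5) in Control, and USP18 5.67 ± 3.35 and 22.2 ± 21.6 CPM. Antigen presentation had a median of -0.63, with CD74 at 29.0 ± 9.38 and 110 ± 84.1 CPM, macrophage markers one of -2.02, with C1QB at 9.44 ± 9.08 and 54.4 ± 62.5 CPM, and apoptosis, p53 and senescence genes one of -0.19, with MDM2, which degrades p53, at 28.2 ± 7.5 and 49.5 ± 9.78 CPM. The log2 fold change of CD74 turned to 0.79 with each cell's own score. Leukocyte-like cells were 14.4% of kept cells in POP and 31.6% in Control. Whether stray leukocyte RNA or doublets account for the lower antigen presentation genes and macrophage markers was not tested. The 3 genes with the smallest p were SH3RF1 at 9.36 ± 1.74 and 23.6 ± 4.21 CPM, the receptor tyrosine kinase MET at 25.6 ± 6.90 and 8.50 ± 2.94 CPM and DIP2B at 103 ± 10.0 and 61.2 ± 11.2 CPM. Control 3 had 29 Schwann-like cells, and 3 counts make 16.2 CPM there. Its SH3RF1 and USP18, each at 17.1 CPM, and its MET, at 11.4 CPM, lay near or below that level. OAS1, USP18, CD74, C1QB and MDM2 were chosen after their values were seen.

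In Schwann-like cells edgeR called 0 of 9094 genes, with 467 at an unadjusted p under 0.05 and adjusted p = 0.729 for SH3RF1, MET and DIP2B. DESeq2 called 6, among them these 3 (adjusted p = 0.0316, 0.0445 and 0.0316). Camera called 4 of 28 lists. Type I interferon was lost without Control 1 (adjusted p = 0.286, median -0.15), macrophage markers without POP 1 (0.136), antigen presentation without POP 1 (0.101), Control 1 (0.425, median -0.187) or Control 3 (0.0989), and apoptosis, p53 and senescence without POP 2 (0.341, median -0.066), Control 1 (0.113), Control 3 (0.354) or Control 5 (0.169), with a median of -0.353 without POP 4. The adjusted p with an estimated correlation was 0.91 for all 4.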

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

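The test of macrophage-like cells among leukocyte-like cells and the fits without and only with the smooth muscle-like clusters with DES were chosen only after their results had been seen. Of 236 groups of samples looked at, 19 held a sample standing far from the others of its group, and chance marks about 1 in 20 groups.

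In fibroblast-like cells, SLC2A8 was 5.48 CPM in POP 4 against 3.08 to 3.38 in the other POP samples, ELN was 421 CPM in POP 3 against 253 to 266, and ESR1 was 525 CPM in POP 1 against 403 to 417. C1QB was 2.60 CPM in fibroblast-like cells of Control 2 against 7.51 to 10.2 in the other Controls. In smooth muscle-like cells of Control 3, ESR1 was 256 CPM against 66.3 to 90.2 in the other Controls, and ACTG2 was 1381 CPM against 4495 to 6895. In vascular endothelial-like cells, CA4 was 20.6 CPM in Control 4 against 40.9 to 49.7 in the other Controls, and APOD was 236 CPM in Control 5 against 754 to 1102. In lymphatic endothelial-like cells, APOD was 267 CPM in POP 2 against 80.6 to 84.8 in the other POP samples, and MT1E was 1139 CPM in POP 3 against 714 to 759. FKBP5 was 79.6 CPM in epithelial-like cells of Control 4 against 67.9 to 69.5 in the other Controls. In Control 1, FKBP5 was 627 CPM in T and NK-like cells against 364 to 380 in the other Controls, 144 CPM in B-like cells against 88.3 to 95.6, and 520 CPM in macrophage-like cells against 280 to 330. ENSMMUG00000052929 had 0 counts in B-like cells of Control 5, which allows up to 24.7 CPM, against 2.82 to 3.88 in the other Controls. In macrophage-like cells, CD163 was 877 CPM in Control 3 against 1291 to 1416 in the other Controls, and APOD was 6.26 CPM in Control 2 against 16.9 to 21.6. USP18 was 60.6 CPM in Schwann-like cells of Control 1 against 10.1 to 17.1 in the other Controls. Neutrophil-like cells were 7.22% of kept cells in Control 2 and at most 1.49% in the other Controls.

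POP 2 and Control 3 shared 135 barcodes, 10.3% of those of Control 3, while the other 35 pairs of samples shared 0 to 42. Of the 117 kept in both samples, 114 were in the same cell class, 97.4%, against 20.9% over the other pairs, and the median UMI count of the shared barcodes was 637 in POP 2 and 25690 in Control 3, and lower in POP 2 for 135 of 135. The UMI counts of the shared barcodes correlated between the 2 samples at Spearman 0.805, against -0.296 to 0.568 over the other pairs with a value. RNA of Control 3 carried into POP 2 would give such values, but the origin of these barcodes was not tested. They stayed in the main fits, so the values of POP 2 carry this limit. Leaving these barcodes out took the macrophage marker list in fibroblast-like cells to an adjusted p = 0.355 and the number of lists called in vascular endothelial-like cells to 0.

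The share of macrophage-like cells, lower in POP by a mean difference of -2.13 points, could follow from lower sequencing depth in POP. This explanation predicted a smaller difference among cells passing the strict filter, and there it was -2.22 points, so it did not shrink. The ranges of the groups overlapped, however, which leaves this open. Another candidate explanation is that the POP suspensions held fewer leukocytes of every kind. Leukocyte-like cells were 14.4% ± 5.78 (SD, n = 4) of kept cells in POP and 31.6% ± 10.7 (SD, n = 5) in Control, exact permutation p = 0.0397. Among leukocyte-like cells the macrophage-like share was 3.58 points higher in POP, exact permutation p = 0.476. This explanation allows that value, but the prediction was written after the class shares were seen. It is therefore no independent test of the explanation.

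The lower contraction genes in smooth muscle-like cells of POP may come from another mix of vascular and visceral smooth muscle. In the clusters without DES the median of the list was -0.20, against -0.43 over all clusters, which neither excludes nor establishes a change of mix. The median less that of all genes was -0.43 with DESeq2's size factors, but the subtraction removes library scaling by construction, so scaling was not tested by it. Of 50 splits of the samples, 50 gave as many called lists as the real 2, with up to 14 in another split. This counts lists of any kind and does not follow the contraction list itself. Chance was therefore not excluded for that list, and the splits did not test it alone.

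The higher CXCL14 in macrophage-like cells of POP might stem from free RNA of fibroblasts. The ratio of levels in macrophage-like to fibroblast-like cells was over 4-fold higher for CXCL14 than for 12 fibroblast markers in 9 of 9 samples. The excess ran from 5.71-fold in Control 1 to 117-fold in POP 3. This argues against free RNA of the fibroblast-like class as a whole as the source. The ratio does not cover doublets or epithelial-like cells, and Control samples passed it too. It therefore does not settle the cause of the rise in POP. The log2 fold change of CXCL14 was 2.34 in macrophage-like cells and 0.20 in fibroblast-like cells, but the classes were not shown to differ, with an exact permutation p = 0.0397 and an adjusted p = 0.106 over 13 such tests. Of 50 splits, 2 gave as many genes as the real 1, with 1 as the highest of the others, but this was 1 of 20 such tests without adjustment and another split gave the same count, so chance was not safely excluded.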

How the results depend on the processing

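The values here cover the settings that were run, the cause of each change was not tested.

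The fit with the replicate number as a block required at least 3 numbers present in both groups and was not run in lymphatic endothelial-like and B-like cells, and at least 50 cells per sample left too few samples of lymphatic endothelial-like cells. Of 204 alternatives for numbers of called genes 171 left the result as it was, of 214 for shares 210, of 214 for numbers of called lists 123, of 769 for single lists 632 and of 2318 for named genes 2160.

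DESeq2 called 11 genes in fibroblast-like, 22 in smooth muscle-like, 12 in vascular endothelial-like, 2 in epithelial-like, 6 in T and NK-like, 2 in B-like, 4 in macrophage-like and 6 in Schwann-like cells. The block, which also leaves out Control 5 for want of a POP sample with its number, gave 2 genes in vascular endothelial-like cells (APOD and CA4) and 0 in macrophage-like cells, against 1 and 0 without Control 5 alone. Without the filter on low counts 106 genes were called in lymphatic endothelial-like and 1 in B-like cells. In lymphatic endothelial-like cells 1 gene was called with doublets kept, 5 with the strict filter and 1 with each cell's own score, where doublets kept and the own score also bring in Control 2 as a further sample, and in macrophage-like cells 0 with doublets kept and 0 with each cell's own score. With 1 sample left out the numbers ran from 0 to 1 in vascular endothelial-like, 3 to 46 in lymphatic endothelial-like, 0 to 2 in B-like and 0 to 1 in macrophage-like cells.

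The adjusted p of the macrophage-like share ran from 0.0873 to 0.429 and its difference from -2.34 to -1.64 points. The fibroblast-like difference turned to -0.0740 points without clusters mostly from 1 sample and ran from -4.20 to 6.80 with 1 sample left out, and the mast-like difference turned to 0.856 with each cell's own score.

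With an estimated correlation and with fry, 0 lists were called in any class. The block gave 12 lists in fibroblast-like, 4 in smooth muscle-like, 17 in T and NK-like, 11 in macrophage-like and 2 in Schwann-like cells. Doublets kept gave 4 in smooth muscle-like, 4 in vascular endothelial-like, 13 in epithelial-like, 9 in T and NK-like, 15 in B-like and 10 in macrophage-like cells. Each cell's own score gave 4 in smooth muscle-like, 3 in pericyte-like, 1 in vascular endothelial-like, 2 in lymphatic endothelial-like, 13 in epithelial-like, 10 in B-like and 8 in Schwann-like cells. No filter on low counts gave 2 in pericyte-like, 8 in epithelial-like, 8 in T and NK-like, 13 in macrophage-like and 8 in Schwann-like cells. At least 50 cells gave 6 in vascular endothelial-like and 1 in Schwann-like cells, and the strict filter 1 in vascular endothelial-like, 8 in epithelial-like and 2 in Schwann-like cells. Without clusters mostly from 1 sample 11 were called in fibroblast-like cells, without the shared barcodes 0 in vascular endothelial-like cells, and in smooth muscle-like cells 4 without and 7 with only the clusters with DES. With 1 sample left out the numbers ran from 3 to 13 in fibroblast-like, 3 to 9 in smooth muscle-like, 0 to 7 in pericyte-like, 0 to 6 in vascular endothelial-like, 3 to 9 in epithelial-like, 2 to 11 in T and NK-like, 3 to 14 in B-like, 1 to 10 in macrophage-like and 0 to 8 in Schwann-like cells.

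Medians of lists reversed in 8 alternatives. In lymphatic endothelial-like cells heat shock turned to -0.21 with doublets kept and -0.24 with each cell's own score, the unfolded protein response to -0.12 with each cell's own score, and fibroblast markers to 0.45 with doublets kept. Proteoglycans in T and NK-like cells turned to -0.0164, collagens in B-like cells to -0.68 and steroid hormone receptors and targets in macrophage-like cells to 0.0764, each without POP 1, and antioxidant genes in B-like cells to -0.030 with each cell's own score. With 1 sample left out the medians ran from -0.0164 to 0.673 for proteoglycans in T and NK-like cells, from -0.677 to 3.4 for collagens in B-like cells and from -0.283 to 0.0764 for the steroid list in macrophage-like cells.

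Among named genes, log2 fold changes reversed mostly where they were near 0. In fibroblast-like cells COL1A1 (-0.001) turned to 0.003 with DESeq2, 0.003 with its size factors, 0.026 without the filter on low counts, 0.0 with the lenient filter, 0.006 with the strict filter, 0.019 without the shared barcodes, 0.23 without POP 2, 0.18 without POP 3, 0.056 without Control 1 and 0.40 without Control 3. COL3A1 turned to -0.20 without POP 1, -0.020 without POP 4, -0.16 without Control 2, -0.031 without Control 4, -0.11 without Control 5 and -0.12 without clusters mostly from 1 sample. FBLN5 turned to 0.024 without POP 2, PGR to -0.016 without POP 4, and ACTA2 to -0.15 without POP 1, -0.067 without POP 3, -0.073 without Control 2, -0.093 without Control 4 and -0.10 without clusters mostly from 1 sample. In smooth muscle-like cells COL1A1 turned to -0.016 and MMP2 to -0.11 without POP 1, ELN to 0.095 without POP 2, 0.027 without POP 3, 0.060 without Control 1, 0.17 without Control 3 and 0.55 with only the clusters with DES, FBLN5 to -0.26 without POP 4 and -0.29 with the block, and TIMP1 to -0.36 without the clusters with DES. In lymphatic endothelial-like cells SDF2L1 turned to -0.20, HSPA5 to -0.15, JUN to 0.20 and HSPD1 to -0.38 with each cell's own score, and HSPD1 to -0.27 with doublets kept. CD2 in B-like cells turned to -0.24 at resolution 0.5, and CD74 in Schwann-like cells to 0.79 with each cell's own score. With 1 sample left out the ranges were -0.352 to 0.396 for COL1A1, -0.202 to 0.428 for COL3A1, -0.31 to 0.024 for FBLN5 and -0.016 to 0.696 for PGR in fibroblast-like cells, and -0.016 to 0.892 for COL1A1, -0.465 to 0.175 for ELN, -0.26 to 0.66 for FBLN5 and -0.11 to 0.467 for MMP2 in smooth muscle-like cells.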

Other observations

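The fall of FKBP5 across classes was noticed after its values were seen, and the test of other steroid targets was written before it was run; the comparison of lymphatic endothelial-like with vascular endothelial-like cells and the clusters described here were chosen after the results were seen.

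FKBP5, a co-chaperone that glucocorticoids and progestins induce, had a log2 fold change below 0 in 10 of 10 classes, from -2.09 in fibroblast-like cells to -0.42 in epithelial-like cells, with an unadjusted p under 0.05 in 9. Over the 7 classes with all samples its mean log2 difference was -1.17, with a permutation p = 0.0079, the smallest 126 arrangements can give, and an adjusted p = 0.923 over 7133 genes. At this smallest p stood 47 genes, where chance gives 56.6. A candidate explanation is lower activity of glucocorticoid or progesterone receptors in POP, and the median of other targets of these receptors was below 0 in 9 of 10 classes, with T and NK-like cells the exception at 0.15. Of 10 such targets 3 to 9 were measured in a class, with 3 in lymphatic endothelial-like and in B-like cells. Of 126 splits of the samples 7 gave as many classes, with 10 in another split, so chance was not excluded. ESR1, the oestrogen receptor, fixed in advance in fibroblast-like and smooth muscle-like cells and chosen after its values were seen in the other classes, had log2 fold changes of 1.66 in T and NK-like cells, 1.58 in vascular endothelial-like cells, 0.85 in fibroblast-like cells, 0.91 in smooth muscle-like cells and 0.57 in pericyte-like cells, none of which passed over all genes with edgeR, while DESeq2 gave an adjusted p = 0.0323 in vascular endothelial-like cells. ESR1 in the remaining classes is not given here, so no rise across all classes is shown. In T and NK-like cells the pericyte marker RGS5 was also higher in POP, at 14.7 against 4.98 CPM. Fibroblast-like cells had ESR1 at 438 and 244 CPM. Whether stray RNA of such cells raised ESR1 in T and NK-like cells was not tested.

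The metallothionein MT1X, called in lymphatic endothelial-like cells, had a log2 fold change of -1.61 at adjusted p = 0.564 in vascular endothelial-like cells, and MT2A one of -1.59, while SDF2L1, with 1.96 in lymphatic endothelial-like cells, had -1.08 in vascular endothelial-like cells. Whether the changes differ between these classes stayed open, since 35 arrangements give no p under 0.0286 and the lowest adjusted p was 0.106. Among the clusters, 1 cluster of smooth muscle-like cells led by RERGL, PRPH and PGF was 9.12% of kept cells in POP and 4.13% in Control, and 1 cluster of macrophage-like cells led by C1QB, MRC1, F13A1 and LYVE1 was 1.77% in POP and 3.25% in Control. Each had an exact permutation p = 0.0159 and an adjusted p = 0.246. A cluster of fibroblast-like cells led by IL33 and PI16 held 845 cells, 95.3% of them from Control 1. The cluster without a class name, led by the muscle progenitor genes MYF5 and PAX7, held 39 cells, 31 of them from POP 4. In fibroblast-like and smooth muscle-like cells, where this was tested, no POP sample was closest to the Control with its own number.

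For the genes called, other splits of the samples were compared with the real one. In lymphatic endothelial-like cells 2 of 35 splits gave as many genes as the real 12, with up to 50 in another split, so chance was not excluded there for genes, while for lists 1 of 35 splits, the real one, gave as many as 9, with 8 as the highest other, but this is the smallest share 35 splits can give and 1 of 20 such tests without adjustment, so chance was not safely excluded. Where the real count was 0, every split gives as many by definition, which tests nothing. For genes this was 50 of 50 in fibroblast-like cells (highest other 5), smooth muscle-like cells (10), pericyte-like cells (14), vascular endothelial-like cells (2), T and NK-like cells (2) and Schwann-like cells (4), and 35 of 35 in epithelial-like cells (37) and B-like cells (2). For lists it was 50 of 50 in pericyte-like cells (13). In other classes the splits with as many lists were 39 of 50 in fibroblast-like cells (real 6, highest other 16), 49 of 50 in vascular endothelial-like cells (2, 19), 34 of 35 in epithelial-like cells (5, 17), 47 of 50 in T and NK-like cells (4, 19), 27 of 35 in B-like cells (6, 18), 47 of 50 in macrophage-like cells (4, 18) and 43 of 50 in Schwann-like cells (4, 15), so chance was excluded in none of these 7 classes. With an estimated correlation nearly all splits called 0 lists, so the high counts of lists go with the preset correlation. For genes, the highest split gave 37 calls in epithelial-like cells against the real 0, and 50 in lymphatic endothelial-like cells against 12. Whether these counts reflect a structure of the samples was not tested.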
